A study of Mus musculus with 7 samples.

How the data were processed

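High-throughput genome-wide translocation sequencing (HTGTS) reads the DNA joined to a fixed bait end, here the JH4 coding end of the Igh locus. It was applied to genomic DNA of bone marrow pro-B cells, sorted as B220+CD43highIgM- from mice of the 129SVE background, per the labels. The 7 libraries fall into WT (n = 3) and VH81X-CBEscr/scr (n = 4). The series title expands CBE as CTCF-binding element. The genotype name is read here as homozygous for a scrambled element beside VH81X, which the labels do not spell out.

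The deposited files list 1 junction per line, which is 1 sequenced read, with its position, strand and sequence. No deposited column holds counts, so all counts were made here by counting lines. Per the submitters' processing notes, reads were aligned with Bowtie2 to mm9, with no version or filter stated. Per the file headers and values, lines marked as duplicates were kept, and they made up 71.8% to 84.8% of a library. All lines were counted in the values reported here.

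The libraries held 31986 to 46915 junctions, and 10942 to 16829 V junctions. A single V junction count of 0 would have allowed a share of up to 0.0178% to 0.0274% of V junctions (3 counts). Intervals are 95% Wilson intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The labels do not say that the libraries are separate mice, so p-values measure only the spread between these libraries.

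Junctions in deletional orientation around the bait on chromosome 12 (mm9) were joined into clusters with gaps of at most 300 bp and at least 10 junctions. All libraries were used without regard to genotype. Junctions between 114471123 and 117838107 were counted as inside the Igh locus. Each cluster from DQ52 to DFL16.1 is treated as a D segment, and each from VH5-1 onwards as a V segment. This gave 158 V segments and 35 D clusters. Clusters in the JH region or between the D and V segments belong to neither. VH81X was found by a hand-written framework sequence in the read consensus, and DQ52 and DFL16.1 by 11 and 23 bases of their core sequences. A genome sequence of the files' build was not used here. Names of 8 V segments came from a gene table of another assembly (GRCm38.p6), by spacing from VH81X within 60 bp, with a largest difference of 48 bp and 1493 bp for the next segment. Of 183 V names in that table, the other 175 were not matched. Other segments are named by V or D and their most frequent junction position. A VH family was assigned to 142 V segments by the closest of 14 framework 3 protein motifs written by hand, not taken from a reference file, and 16 were not assigned by motif. VH15 and VH16 had no motif, so a segment of either family would be left unassigned or placed in another family. VH81X, 1 of the 16 segments, was tied between motifs and was placed in VH5 by its table name, so that 15 stayed without a family. The prey bases of 92.3% of V junctions and 99.0% of D junctions matched their own segment's consensus better than any other (bwa 0.7.19). This rate was far lower in some distant V segments, such as 7.41% for V_116368841 and 8.64% for V_117135978, so counts of such segments are less certain. The median mismatch to the files' reference was 0.527% over the 80 V segments up to position 116151874 and 3.87% over the 78 from 116166928. The cause of this step was not tested. Positions and distances are those of the files' reference, called mm9 after the processing notes and not checked against mm9 itself.

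Per segment, limma-voom (limma 3.58.1, R 4.3.3) compared the genotypes with V junctions (or D junctions) as library size, over segments with at least 10 junctions on average in either group. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and limma's tests are two-sided. Single shares and shares of VH groups were compared by two-sided exact permutation tests of the group means of log2 share over all 35 splits of the 7 libraries, with 0.0286 as the smallest possible p. Such a test cannot pass 0.05 where 1 library is left out, since 3 against 3 allows 0.1 and 2 against 4 allows 0.0667. Figures and tables used Python 3.11.15, SciPy 1.17.1 and pandas 2.3.3.

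Loss of an abundant V segment raises the share of every other segment, so each V result was also computed with VH81X left out of the library size. This moved the median log2 fold change of the 129 tested V segments from -0.04 to -0.18.

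The methods were tested on simulated data with the real means and library sizes. In each of 20 draws, 20 V segments or 7 D clusters were changed 2- or 4-fold, of a median of 126.5 and 23.5 tested. Recovery was computed only with the totals that the counts were drawn from as library size, not with summed junctions. For V segments, limma-voom then recovered 84.9% of 2-fold and 99.5% of 4-fold changes. For D segments it recovered 86.3% of 2-fold and 100% of 4-fold changes. With the totals that the counts were drawn from as library size, 6.85% of V calls and 9.29% of D calls were on unchanged segments. With summed junctions as library size, the way the real data were fitted, 18.1% of V calls and 54.3% of D calls were on unchanged segments. The first pair of rates was computed after the second had exceeded a limit set for the simulation.

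The groups, the tests, the cluster rule, the low-count filter, the distance and family groups and the rule for named segments were fixed before the data were examined. The rule names VH5-1, VH81X, the 10 segments next upstream, the 5 most used in WT, up to 10 higher and 10 lower segments past the threshold, and every D segment that can be told apart. Told apart was defined after the clusters were seen, as at least 1000 junctions, with the prey of at least 90% of them matching their own segment best. This leaves 12 of 13 D segments. The naming tolerance and the family motifs were also set after the reads were seen, before any comparison of genotypes by family. The alternatives fixed in advance were counting distinct junctions, leaving out each library, the replicate number as a block, thinning to 31986 junctions, other library sizes, orientations, filters, clusters and tests, and prey matching 1 segment best. Added after the data were seen were lines not marked duplicate, the sequencing run as a random block, limma on group shares, the split of VH2 at 100 kb, and leaving out a position on chromosome 4.

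Read names showed 4 sequencing runs, and 0 held both genotypes. VH81X-CBEscr/scr replicates 1 and 2 shared a run, as did replicates 3 and 4, and as did WT replicates 2 and 3. A value within a run could not be computed, so run was fitted as a random block. The estimated correlation within runs was negative, at -0.184 for V segments and -0.569 for D clusters, so this fit is no more cautious and does not account for run.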

Results

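Junctions between the JH4 coding end and the rest of the genome were sequenced in 3 WT and 4 VH81X-CBEscr/scr libraries of pro-B cells, and n counts libraries. The series design asks how often each VH segment is used in the 2 genotypes. A junction of JH4 to a D segment stands for a DJ join, and a junction to a VH segment for a V(D)J join. WT replicates 1 to 3 held 40613, 33782 and 46915 junctions, and VH81X-CBEscr/scr replicates 1 to 4 held 38229, 31986, 35057 and 38209. V junctions numbered 16829, 10942 and 14847 in WT, and 12012, 11646, 13003 and 15677 in VH81X-CBEscr/scr. D junctions numbered 22801, 22120 and 31101 in WT, and 25121, 19545, 21015 and 21476 in VH81X-CBEscr/scr. Repeated reads were frequent. WT replicate 2 held 8551 distinct junctions, against 13601 to 22631 in the other libraries.

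VH81X was the most used VH segment in WT and was rare among V junctions in VH81X-CBEscr/scr. This comparison addresses the segment beside the altered element. VH81X (chromosome 12, junctions at 114836368 to 114836404, mm9) took 9.44% ± 0.627 (SD, n = 3) of V junctions in WT and 0.181% ± 0.140 (SD, n = 4) in VH81X-CBEscr/scr, a 52.1-fold lower mean. The log2 share differed by -6.00, every mutant library lay below every WT library, and the exact permutation p (two-sided) was 0.0286, the smallest that 35 splits allow. Among lines not marked duplicate, VH81X took 4.95% ± 0.757 and 0.244% ± 0.142, a 20.3-fold lower mean (log2 difference -4.51). Among distinct junctions it took 8.20% ± 0.626 and 0.188% ± 0.120, a 43.65-fold lower mean (log2 difference -5.65). In limma-voom over 129 VH segments, the log2 fold change of VH81X was -5.95 (SE 0.294, adjusted p 8.64e-69), a p that rests on a spread shared across segments. VH81X junctions were still found in each mutant library, with 46, 8, 14 and 26 in replicates 1 to 4, and their source was not settled. The share of VH81X in VH81X-CBEscr/scr replicate 2, the lowest, was 0.0687% (95% Wilson interval 0.0348% to 0.136%), and in replicate 1, the highest, 0.383% (0.287% to 0.510%). All 7 intervals for VH81X kept the genotypes apart, with 8.56% as the lowest WT bound.

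VH2-2, VH5-4 and VH2-3, which lie next upstream of VH81X, took a larger share of V junctions in VH81X-CBEscr/scr. Of 129 VH segments tested with limma-voom, 5 were higher and 1, VH81X, was lower in VH81X-CBEscr/scr, and 17 had an unadjusted p under 0.05. VH2-2, which lies 9.77 kb upstream of VH81X (114846136 to 114846530), rose from 5.59% ± 0.406 (SD, n = 3) to 11.6% ± 1.82 (SD, n = 4) of V junctions, with a log2 fold change of 1.05 (SE 0.140, limma-voom adjusted p 1.56e-11) that was 0.57 (adjusted p 3.52e-04) among lines not marked duplicate. VH2-2 thereby became the most used VH segment in VH81X-CBEscr/scr. VH5-4, 19.0 kb upstream (114855232 to 114855390), rose from 2.996% ± 0.559 to 4.73% ± 0.471, with a log2 fold change of 0.65 (SE 0.152, limma-voom adjusted p 8.34e-04). VH2-3, 32.7 kb upstream (114869098 to 114869166), rose from 2.13% ± 0.174 to 3.27% ± 0.271, with a log2 fold change of 0.61 (SE 0.160, limma-voom adjusted p 0.00465). VH2-2, VH5-4 and VH2-3 were each higher in 4 of 4 mutant libraries than in every WT library, a separation that chance gives in 5.71% of splits in either direction. V_114961492, a VH5 segment 125 kb upstream, rose from 1.27% ± 0.438 to 1.91% ± 0.545 with a log2 fold change of 0.60 (limma-voom adjusted p 0.0277), and 2 of 4 mutant libraries lay above every WT library. V_115608445, a VH3 segment 772 kb upstream, rose from 1.15% ± 0.430 to 1.73% ± 0.196 with a log2 fold change of 0.61 (limma-voom adjusted p 0.0277).

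All 10 segments next upstream of VH81X had a positive log2 fold change, and 4 of them passed the threshold. VH5-6 had a log2 fold change of 0.46 (limma-voom adjusted p 0.122) and VH2-4 one of 1.06 (adjusted p 0.128), and both were higher in 4 of 4 mutant libraries than in every WT library. VH5-9 (0.16), V_114976040 (0.65), V_114998634 (0.43) and V_115006778 (0.79) were also not past the threshold, with limma-voom adjusted p from 0.274 to 0.959. VH5-1, a pseudogene in the gene table, lies 5.57 kb downstream of VH81X and showed no detectable change, at 0.404% ± 0.276 in WT and 0.265% ± 0.0806 in VH81X-CBEscr/scr (log2 fold change -0.47, limma-voom adjusted p 0.694). V_115453076, a VH2 segment 617 kb upstream that was among the 5 most used in WT, had a log2 fold change of 0.30 (limma-voom adjusted p 0.390). With VH81X left out of the library size, VH2-2 (0.90, limma-voom adjusted p 7.10e-09) and VH5-4 (0.51, adjusted p 0.0278) stayed past the threshold, while VH2-3 (0.47, adjusted p 0.0743), V_114961492 (0.46, adjusted p 0.147) and V_115608445 (0.46, adjusted p 0.147) did not.

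Single libraries decided some of these calls. V_114961492 was not past the limma-voom threshold without WT replicate 1 (log2 fold change 0.35), mutant replicate 2 (0.44) or mutant replicate 3 (0.55). V_115608445 was not past it without WT replicate 2 (0.38), WT replicate 3 (0.55), mutant replicate 3 (0.64) or mutant replicate 4 (0.51). VH5-1, V_114998634 and VH5-6 passed with 1 library left out, VH5-1 without WT replicate 2 (log2 fold change -1.01), V_114998634 without WT replicate 3 (0.85) and VH5-6 without mutant replicate 1 (0.54). V_117124058 and V_115694901, named after their values were seen, also passed with 1 library left out. V_117124058, a VH1 segment 2288 kb upstream at 0.162% ± 0.119 in WT and 0.312% ± 0.0475 in VH81X-CBEscr/scr, had a log2 fold change of 1.18 (limma-voom adjusted p 0.0529) and passed in 6 alternatives, among them without WT replicate 1 (1.73), without mutant replicate 1 (1.26) and among lines not marked duplicate (1.02). Of the V_117124058 junctions, 81.6% matched their own segment's consensus best. V_115694901, 859 kb upstream, had a log2 fold change of 1.25 (limma-voom adjusted p 0.274) and passed without mutant replicate 1 (1.77). VH81X, VH2-2, VH5-4 and VH2-3 were past the threshold with each library left out.

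**Figure D1:**
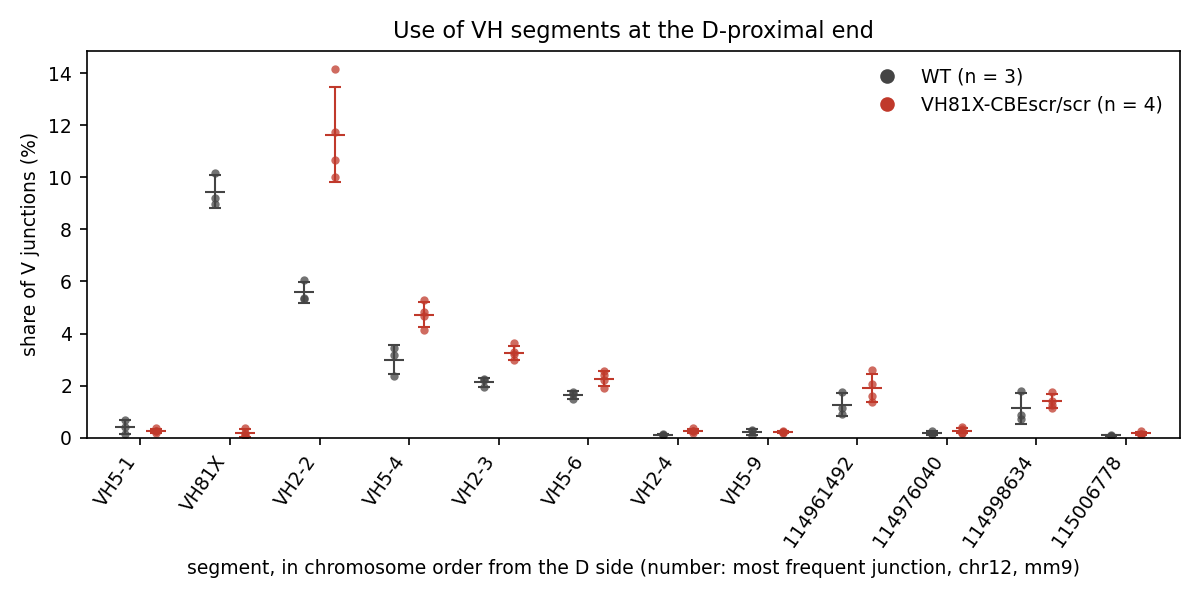
Share of V junctions (%) for VH5-1, VH81X and the 10 segments next upstream, in chromosome order, with a point per library and bars for the mean ± SD of WT (n = 3) and VH81X-CBEscr/scr (n = 4). VH81X falls from 9.44% to 0.181% and VH2-2 rises from 5.59% to 11.6%.

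**Figure D2:**
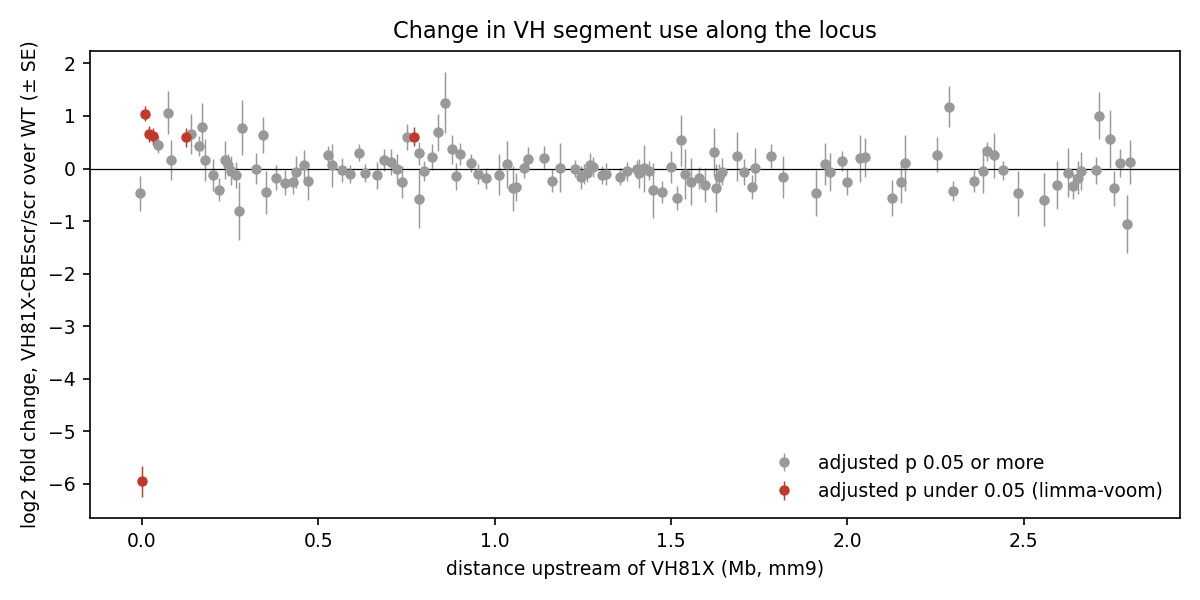
Log2 fold change (VH81X-CBEscr/scr over WT, ± SE, limma-voom) of the 129 tested VH segments against their distance upstream of VH81X (Mb, mm9), with red for an adjusted p under 0.05. VH81X lies at -5.95, and 4 of the 5 higher segments lie within 200 kb.

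As a group, the 6 VH segments within 100 kb upstream of VH81X took more of the V junctions in VH81X-CBEscr/scr. The segments within 100 kb rose from 12.7% ± 1.09 (SD, n = 3) to 22.4% ± 2.29 (SD, n = 4), a log2 difference of 0.82 that stayed positive under every library size tried. This difference was 0.77 among distinct junctions and 0.48 among lines not marked duplicate. VH2-2 belongs both to these 6 segments and to the VH2 family, and made up most of the rise in share of each. Results for these groups are therefore not independent of that for VH2-2. The VH2 family rose from 14.6% ± 1.73 to 22.8% ± 1.29 (log2 difference 0.65, also positive under every library size, 0.56 among distinct junctions and 0.30 among lines not marked duplicate). Split after these values were seen, the 3 VH2 segments within 100 kb rose from 7.84% ± 0.522 to 15.2% ± 1.93, while the other 14 took 6.74% ± 1.33 and 7.60% ± 0.739 (log2 difference 0.19, exact permutation p 0.257), or differed by 0.046 with VH81X left out of the denominator. The VH5 family, which contains VH81X, fell from 25.1% ± 2.23 to 18.4% ± 0.621 (log2 difference -0.44), but differed by 0.09 with VH81X left out. VH9, at 4.27% ± 0.355 in WT and 4.97% ± 0.140 in VH81X-CBEscr/scr, and VH14, at 5.58% ± 0.211 and 4.98% ± 0.328, did not pass the threshold with V junctions as denominator. The most distant segments, over 1.5 Mb upstream, took 20.1% ± 1.62 in WT and 19.0% ± 0.376 in VH81X-CBEscr/scr (exact permutation p 0.229), and VH1, the largest family, took 26.8% ± 2.25 and 25.1% ± 0.434 (exact permutation p 0.2). With VH81X left out of the denominator, the segments over 1.5 Mb upstream took 22.2% ± 1.79 and 19.0% ± 0.395 (log2 difference -0.22), those at 1 to 1.5 Mb 27.4% ± 2.65 and 23.3% ± 0.666 (-0.23) and VH1 29.6% ± 2.50 and 25.2% ± 0.442 (-0.23), while the segments within 100 kb took 14.0% ± 1.19 and 22.4% ± 2.29 of the same total, which leaves less for all others together. The 3 groups passed in neither test, and each had every mutant library below every WT library, an exact permutation p of 0.0286 (adjusted p 0.0857) and a limma adjusted p of 0.056 to 0.059. Of 21 groups, 0 passed the Benjamini-Hochberg threshold in the exact permutation test, and 6 (VH81X, the segments within 100 kb, VH2, VH5, VH9 and VH14) had an unadjusted p of 0.0286, each with an adjusted p of 0.1. At this smallest p, 12 groups would only have reached an adjusted p of 0.05, not one under it, so more than 12 were needed to pass. Limma on the log2 shares, added after these counts were seen, called 4 groups, namely VH81X, the segments within 100 kb (adjusted p 0.00102), VH2 (adjusted p 0.00182) and VH5 (adjusted p 0.00403). With VH81X left out of the denominator, limma called VH81X, the segments within 100 kb (log2 difference 0.68, adjusted p 0.00327), VH2 (0.51, adjusted p 0.00738) and VH14 (-0.30, adjusted p 0.026). With VH81X kept in the denominator, the log2 difference of VH14 was -0.11 among distinct junctions and 0.0045 among lines not marked duplicate. V_116193011, 1 of the 5 VH14 segments, was placed there with a lead of 2 residues over the next motif, the smallest accepted. Its identity to the motif was 78.1%, against 90.6% to 100% for the other VH14 segments, so its family is uncertain.

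The balance of V(D)J and DJ joins did not differ detectably between the genotypes. V junctions made up 35.96% ± 5.65 (SD, n = 3) of V and D junctions in WT and 37.5% ± 4.05 (SD, n = 4) in VH81X-CBEscr/scr. The log2 difference was 0.066, smaller than the spread between libraries, with a two-sided exact permutation p of 0.6. WT replicate 1, at 42.5%, and VH81X-CBEscr/scr replicate 4, at 42.2%, were the highest libraries of their genotypes. The log2 difference was 0.19 without WT replicate 1, -0.0050 without WT replicate 3 and -0.013 among lines not marked duplicate.

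Use of D segments was similar in both genotypes, with 1 lower segment, D_114687612. This comparison asks whether the DJ joins of the same cells changed. Of 24 D clusters tested with limma-voom, 0 were higher and 1 was lower, and 2 had an unadjusted p under 0.05. D_114687612 (114687607 to 114687672, upstream of DQ52) fell from 4.03% ± 0.230 (SD, n = 3) to 2.86% ± 0.259 (SD, n = 4) of D junctions, with a log2 fold change of -0.50 (SE 0.0967, limma-voom adjusted p 0.00391), and 4 of 4 mutant libraries lay below every WT library. Over 16 alternatives its log2 fold change ran from -0.55 to -0.28, and it passed the threshold in 14. In the exact permutation test per cluster, D_114687612 reached the smallest p, 0.0286, and 0 of 24 passed after adjustment, with 1 at an unadjusted p under 0.05. In simulated D counts fitted in the same way, with 7 clusters changed 2- or 4-fold per draw, 54.3% of calls lay on unchanged clusters. The real fit called 1 cluster, so this rate does not give the probability that the call of D_114687612 is false. DFL16.1, the most used, took 23.2% ± 0.101 in WT and 22.1% ± 1.42 in VH81X-CBEscr/scr (log2 fold change -0.08, limma-voom adjusted p 0.568). DQ52 took 5.61% ± 1.29 and 5.69% ± 0.667 (log2 fold change 0.06, limma-voom adjusted p 0.872). The 11 D segments other than D_114687612 had log2 fold changes from -0.14 (D_114719358) to 0.21 (D_114690286).

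**Figure D3:**
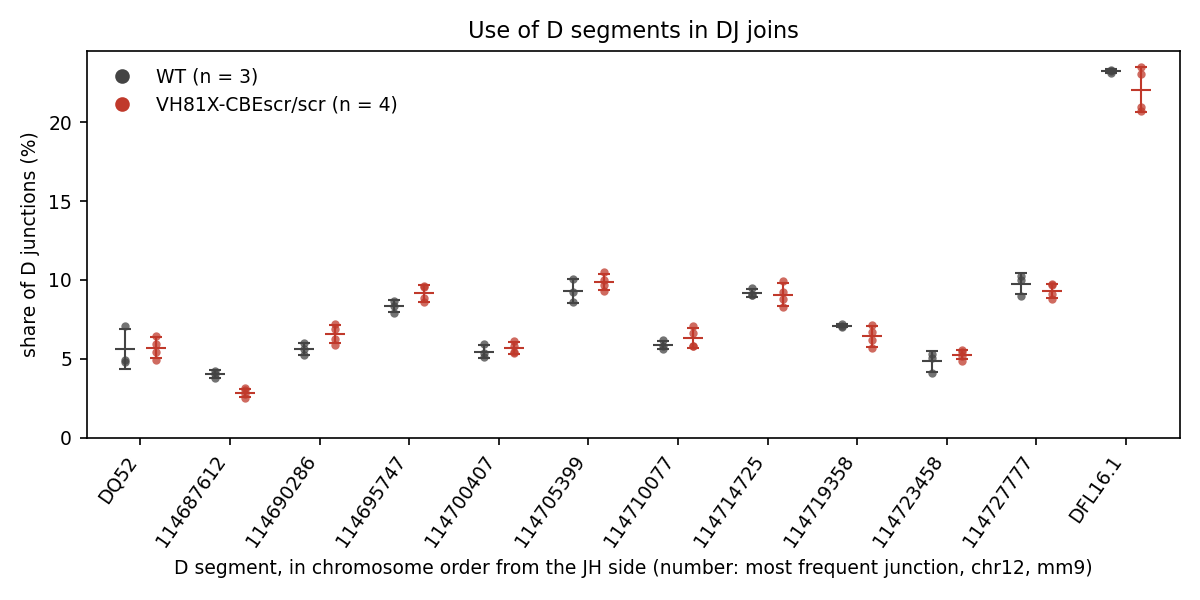
Share of D junctions (%) for the 12 D segments that could be told apart, in chromosome order from the JH side, with a point per library and bars for the mean ± SD of WT (n = 3) and VH81X-CBEscr/scr (n = 4). D_114687612 falls from 4.03% to 2.86%.

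Junctions outside the Igh locus, the background of the assay, were rare in both genotypes. They made up 0.123% ± 0.0218 (SD, n = 3) of junctions in WT and 0.235% ± 0.131 (SD, n = 4) in VH81X-CBEscr/scr, with a two-sided exact permutation p of 0.286. VH81X-CBEscr/scr replicates 3 and 4, sequenced in the same run, held 0.334% and 0.364%, and replicates 1 and 2 held 0.126% and 0.119%. The log2 difference of 0.76 became 0.48 without mutant replicate 4.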

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

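Of the tests here, those of the share left free by VH81X, of reads shared between segments, of carry-over of amplified product, of other splits of the libraries and of the sequencing run were chosen only after the result was seen.

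The 6 segments within 100 kb upstream of VH81X took a larger share of V junctions in VH81X-CBEscr/scr. If the share left free by VH81X spread over all other V segments in proportion to their use, no excess would remain with VH81X out of the denominator. The log2 difference was still 0.68 (limma on log2 shares, SE 0.102), which argues against such an even spread. A spread of the freed share mainly to the nearest segments would also give an excess there, so this value does not exclude the loss of VH81X as the cause. With VH81X kept in the denominator, the log2 difference was 0.82 over all V junctions. On that denominator it was 0.87 among out-of-frame V junctions, which argues against later selection of in-frame joins as the whole cause. It was 0.79 when only prey matching 1 segment best was counted, which argues against reads shared between near-identical segments. The values 0.87 and 0.79 are not comparable with 0.68, since they include share left free by VH81X. In WT, VH81X took 14.4% of out-of-frame V junctions and 10.4% of those matching 1 segment best. The number of changed VH segments, 6, was reached by 1 of the 35 splits of the 7 libraries, the real one, and the highest other split gave 0. This is the lowest share that 35 splits allow, so a random grouping of these libraries is not excluded. The count of 6 includes VH81X itself, and the real split also separates the sequencing runs. A candidate explanation is that the altered element leads to more joining of the segments next upstream, but run is confounded with genotype since 0 of 4 runs held both, and other differences between the samples were not tested.

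VH81X junctions remained in every VH81X-CBEscr/scr library, 94 in all and 51 distinct. Of the distinct ones, 0 were also found in a WT library, which allows a share of up to 5.88%, while 57.5% to 89.96% were found again when as many lines were drawn from a WT library, which argues against carry-over of these libraries' amplified product. The share was -0.0289 percentage points from that of other V junctions, which had been set in advance to count against any carry-over from WT libraries, but WT libraries shared only 0.229% of distinct VH81X junctions with each other, so WT genomic DNA would not be seen by it and stays open. The prey of 100% of the 94 matched VH81X better than any other segment, which argues against reads of a near-identical segment. Rare joining of VH81X without the intact element, or a small number of cells of another genotype, could each leave such junctions, and no test here separates these explanations.

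A single position on chromosome 4 (64808501) recurred in VH81X-CBEscr/scr replicates 3 and 4, where it held 0.0770% and 0.126% of all junctions. The V and D comparisons do not use it, but the reported share of junctions outside the Igh locus includes it. The bait part of the lines at this position ended a median of 75 bases short of the most frequent bait end, with a median of 28 prey bases. A join at the JH4 coding end is therefore not shown. The position held 0 junctions in WT and 0 in the other run of VH81X-CBEscr/scr libraries, so it follows the sequencing run that replicates 3 and 4 share. Of its 75 lines, 42.7% were distinct junctions, or 2.34 lines per distinct junction, close to 2.09 and 2.34 in the whole libraries, but the lines held only 3 pairs of position and place of the prey in the read, so few and many starting molecules cannot be told apart. A source shared by that run's libraries may explain the position, and no biological explanation was tested. Both libraries also held more junctions outside the Igh locus without this position, at 0.257% and 0.238%.

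The share of V_115608445 in VH81X-CBEscr/scr replicate 4 was 2.02% and lay far from the other 3 mutant libraries, which held 1.61% to 1.66%. This was 1 of 28 groups of 4 libraries examined this way, and chance gives about 1 in 20.

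The lower use of D_114687612 was the 1 called change among D clusters, and 6 of the 35 splits of the libraries, the real one included, called at least 1 cluster, with 1 as the highest other value. Random grouping is therefore not excluded for this count.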

How the results depend on the processing

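Lines not marked duplicate, the sequencing run as a random block, limma on group shares and leaving out the chromosome 4 position were chosen only after the data were seen. Lower VH81X use kept its direction and its side of the threshold under all 17 alternatives, where the 7 fits with a library left out and the block fits used limma-voom since the permutation test cannot pass 0.05 with a library left out. Its log2 differences ran from -6.46 to -5.63 with each library left out and from -6.03 to -4.51 (lines not marked duplicate) in the other 10, and the group comparison gave -6.14 with VH81X left out of the denominator. The count of changed VH segments was 6 in the reported fit, 4 (without mutant replicate 3) to 9 (without mutant replicate 1) with each library left out, 2 with V and D junctions together as library size, 3 with VH81X left out of the library size, and 0 in the exact permutation test per segment, where 7 had an unadjusted p under 0.05 and 129 tests at a smallest p of 0.0286 keep any from passing; its other alternatives, apart from the replicate block (2), gave 4 to 8 (sequencing run as a random block, which estimated negative correlations of -0.184 for V and -0.569 for D and so does not account for run). VH81X and VH2-2 passed in 22 of 23 alternatives, VH5-4 in 20, VH2-3 in 19, V_114961492 in 13 and V_115608445 in 11. Over these alternatives the log2 fold change ran from 0.57 to 1.11 for VH2-2, 0.41 to 0.77 for VH5-4 and 0.47 to 0.68 for VH2-3. It ran from 0.31 to 0.88 for V_114961492 and from 0.22 to 0.91 for V_115608445. The count of changed D clusters was 1 with each library left out and 0 in the exact permutation test per cluster (1 at an unadjusted p under 0.05). The count of changed VH groups was 0 by permutation and 4 by limma on log2 shares, with or without VH81X in the denominator; fits with each library left out also used limma and gave 4 to 5 (without WT replicate 1), so the test, not the library, sets this difference from 0. The log2 difference in V share of V and D junctions, 0.066 and not called, reversed to -0.0071 with distinct junctions and to -0.013 with lines not marked duplicate, and ran from -0.0050 (without WT replicate 3) to 0.19 (without WT replicate 1); the cause was not tested. The share outside the Igh locus ran from 0.48 to 1.02 with each library left out and was not called in any alternative that had a test. Of the other values of named segments, 473 were the same, 4 passed the threshold only in the alternative, 33 passed it only in the reported fit, and 0 reversed among called values. Among lines not marked duplicate, the log2 difference of the segments within 100 kb was 0.48 in place of 0.82 and that of VH2 0.30 in place of 0.65. Among distinct junctions, fixed in advance as an alternative, these differences were 0.77 and 0.56. The duplicate mark left fewer lines than there were distinct junctions in each library, with 11433 against 22531 in WT replicate 1. The cause of the smaller differences among lines not marked duplicate was not tested. Depth limits a V count of 0 to a share of up to 0.0178% to 0.0274% per library, for counting error only.

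No pairing of the libraries by replicate number was seen, with correlations of same-numbered libraries of -0.285, -0.00725 and 0.12. Those of differently numbered libraries ran from -0.257 to 0.319, so so few libraries cannot show that pairing is absent. With the replicate block, 2 VH segments (VH81X and VH2-2), 0 D clusters (1 at an unadjusted p under 0.05) and 3 VH groups passed, the log2 fold change of VH81X was -5.83 (limma-voom adjusted p 0.00507), and the V share and the share outside the Igh locus stayed uncalled.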

Other observations

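Of the tests here, those of joining without later selection and of distance from VH81X were chosen only after the result was seen.

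The share of V junctions in frame was lower close to VH81X. It could be read for 99.6% of V junctions. In WT, 31.1% ± 3.37 (SD, n = 3) of VH81X junctions were in frame, 39.7% ± 1.82 of those of the segments within 100 kb upstream and 59.8% ± 3.003 of those further upstream. Joining alone would give 1 in 3. The lowest WT library held 56.9% in the segments further upstream, so joining without later selection is argued against there, and selection of cells with an in-frame join may contribute. Among the 61 segments with at least 500 junctions, the in-frame share was 30.5% for VH81X, 29.4% for V_115999120 (VH12) and 31.8% for V_116240676 (VH1), so the low share was not confined to segments near VH81X.

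The in-frame share of the segments within 100 kb was 37.9% ± 4.29 (SD, n = 4) in VH81X-CBEscr/scr, and the exact permutation p between genotypes was 0.743 (two-sided, adjusted p 0.994 over 6 comparisons). A change of this share by genotype could not be shown. A p of 0.05 or more had been set in advance as evidence against such a change, but a missed threshold with 7 libraries does not show equal shares, so the question stays open.

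Across the 127 tested segments upstream of VH81X, log2 fold changes fell with distance, with Spearman's rho of -0.26 (permutation p 0.00315, adjusted 0.0063 over 4 relations) and Pearson's r of -0.26 (permutation p 0.00309). Segments are not independent replicates, and many junctions of some distant segments did not match their own segment best. Without the 6 segments within 100 kb, rho was -0.17 (permutation p 0.0643) and r -0.16 (permutation p 0.0768), over 121 segments. A gain limited to the first 100 kb had been set in advance to show as a p of 0.05 or more, which was met, but a missed threshold does not show that no trend remains, so a trend over a longer range may exist.

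Some junctions joined the JH4 bait to the JH region itself in the opposite orientation. They made up 1.53% ± 0.128 (SD, n = 3) of junctions in WT and 1.88% ± 0.201 (SD, n = 4) in VH81X-CBEscr/scr, with a two-sided exact permutation p of 0.0857. Of 4563 such lines, 2130 were distinct, and 77.1% had at least 10 bases between bait and prey.

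Besides the position on chromosome 4, 3 positions outside the Igh locus recurred. A position on chromosome 19 (61308325) held 40 lines spread over all 7 libraries. A position on chromosome 14 (54179916) held 23 lines, with 14 in WT replicate 1, 8 in WT replicate 3 and 1 in VH81X-CBEscr/scr replicate 3. A position on chromosome 1 (50655932) held 12 lines, all in VH81X-CBEscr/scr replicates 3 and 4, with a median of 30 prey bases. Its bait part ended a median of 48 bases short of the most frequent bait end, against 0 and -1 at the positions on chromosomes 19 and 14.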
